A study of Arabidopsis thaliana with 12 samples.

How the data were processed

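The data are droplet-based single-cell RNA counts (10x Genomics) from root protoplasts of Arabidopsis thaliana. Protoplasts are cells whose walls were digested away. Seedlings were 7 days old, about 3000 roots were harvested per library, and 1.5 cm of each root from the tip was used, per the labels. The wild type was Col-0. The mutant fer-4 carries a disrupted FERONIA (FER) gene, which encodes a receptor kinase of the plasma membrane. RALF1, a peptide hormone bound by FER, was given at 2 uM for 2 h, and mock treatment was the control. Each genotype had a mock and a RALF1 group, which made 4 groups of 3 libraries. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

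The deposited matrices hold whole-number counts of unique molecular identifiers (UMIs) per gene and barcode, made by the authors with Cell Ranger, per the file headers and the submitters' processing notes. The other deposited files list the identifiers and symbols of the 32833 genes and the barcodes of each matrix, per the file headers. The notes name Cell Ranger 3.1.0, STAR without a version, and Seurat 3.1.1, while the file headers name Cell Ranger 5.0.0. They name the builds TAIR9 and TAIR10 without saying which served for alignment, and the annotation is not given in the sources used here. The deposited counts were used without any scaling by the authors. Gene names come from the deposited files. Of the 32833 identifiers, 32548 matched a gene table of assembly TAIR10.1, which was used only for names and for the order of neighbouring genes. Counting by strand is not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart.

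Of 137060 deposited barcodes, 136020 were kept, with at least 500 detected genes and at most 5% mitochondrial UMIs. The second filter took 771 barcodes from fer-4 RALF1 replicate 2, of 1040 removed in all. Doublet calling by simulated doublets, at an expected 0.8% per 1000 barcodes, marked at most 2 barcodes in any library. It had not worked, and no barcode was removed as a doublet. Totals per library ran from 65.3 to 182.6 M UMIs. A gene's CPM was its UMIs divided by the library's total, on the usual scale. Where edgeR values are given, the total was multiplied by the TMM normalization factor, which lay between 0.956 and 1.05. Values are means ± SD over 3 libraries unless stated, and fold changes are log2 ± SE. Counts and floors cover sampling of molecules alone.

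Cells were clustered in Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, pandas 2.3.3) on 2000 variable genes and 30 principal components, centred per library. Up to 2500 cells per library defined the axes, with 20 neighbours per cell and Leiden resolution 1. The 1748 genes called between fer-4 and Col-0 beyond 2-fold were left out of clustering. This gave 31 clusters. A cluster was named from 10 marker sets when at least 3 markers and 25% of the markers of its set were at least 2-fold above the other clusters and seen in over 5% of its cells. The 25% limit was chosen after the clusters were seen and alone kept clusters 2, 12 and 14 unnamed. In all 14 clusters, with 82300 cells, had no name. The largest, cluster 1, held 33881 barcodes with a median of 4493 UMIs, and 0 markers of any set met the limits in it. The 17 named clusters formed 7 classes (endodermis-like, non-hair epidermis-like, pericycle-like, phloem and companion cell-like, root cap-like, root hair cell-like and xylem-like cells) with 53720 cells. They are named here without the suffix. No cluster met the limits for the marker sets of cortex, of procambium and early stele, or of dividing meristem cells. Only 3 cortex markers could be used, so a cortex cluster needed all 3, and cluster 7 had 2. The lack of a cortex class thus says little on whether cortex cells were present.

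Counts were summed per library over all kept cells (whole root) and per library and class. They were tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood test, TMM, filter on low counts) on all 12 libraries with 1 mean per group. A class was fitted where every library held at least 20 of its cells. The comparisons were RALF1 against mock in Col-0, the same in fer-4, the difference between these responses (the interaction), and fer-4 against Col-0 in mock. Benjamini-Hochberg adjustment ran over all genes tested in a comparison, and a gene was called at an adjusted p under 0.05. Shares of cells per class were tested with edgeR on cell counts per library. For 4 genes named in advance (FER, PIF3, PIEZO, RALF1) the test within classes was adjusted over the classes. DESeq2 1.42.0 was run as another tool. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry. Lists of fewer than 5 tested members had no set test. The edgeR tests of genes and of shares were run on simulated data. Camera, fry, DESeq2 and the share test with the replicate block described below were not. Changed genes were drawn from those with a mean of at least 10 CPM. Of these, 54% of genes changed 2-fold and 99% of genes changed 4-fold were found for RALF1 in Col-0, against 11% and 86% for the interaction and 41% and 100% for fer-4 against Col-0. Each run held 100 genes of each fold at once, which eases the adjusted threshold for the 2-fold genes. For these fits the libraries were drawn without pairs, unlike the real ones. The percentages thus do not give the power of the real comparisons.

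The 17 lists held 264 genes: FER receptor complex and partners, RALF peptides, PIF and light signalling, mechanosensitive channels and touch genes, early wound and stress transcription factors, jasmonate synthesis and response, ethylene synthesis and response, auxin response and transport, abscisic acid response, pattern-triggered immunity, cell wall remodelling, root hair growth, heat shock proteins, iron deficiency response, phosphate starvation response, cell division, and photosynthesis as a sign of shoot tissue. Some genes sit in several sets: for example COBL9, XTH12 and PRP1 are in the root hair list and among the root hair markers. Named genes followed a rule. Per whole-root comparison these were the 8 largest rises and 8 largest falls among called genes with a mean of at least 10 CPM and no overlap between the groups, the 4 genes above, and up to 4 called members per list, or else the member with the largest mean. Per class up to 3 rises and 3 falls were named. Organelle genes were left out of the named genes. The groups, lists, markers, tests, naming rule and the first set of other settings were fixed before the data were examined. Genes named outside the rule are said to be chosen after their values were seen.

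Same-numbered libraries were checked for pairing from the correlation of their deviations from the group means over 8864 genes. Between mock and RALF1 it was 0.874, 0.899 and 0.573 in Col-0 and 0.588, 0.478 and 0.683 in fer-4. Between genotypes it was 0.624, -0.0513 and 0.0260 in mock and 0.247, -0.0673 and 0.303 with RALF1. By these correlations the numbers pair mock and RALF1 libraries within a genotype, as read from the data, and libraries across genotypes only in part. In replicate 1, barcodes with at least 10000 UMIs made up 31.8% of Col-0 mock, 31.2% of Col-0 RALF1, 36.8% of fer-4 mock and 35.4% of fer-4 RALF1. In replicate 3 they made up 14.2%, 19.0%, 18.6% and 20.6% in the same order. A batch shared by the genotypes is thus not excluded. A fit with the replicate number as a block within each genotype was added after this check. Its values stand beside a result, or in the section on processing, where it changed a call.

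The other settings fixed in advance were RLE in place of TMM, no filter on low counts, the replicate number as 1 block over all libraries, only the groups compared, all deposited barcodes, a stricter cell filter (at least 1000 genes and 2000 UMIs, at most 2% mitochondrial UMIs), equal numbers of cells per class and library, DESeq2, other clustering settings (resolution 0.5 and 2, called genes kept, no centring), an estimated correlation for lists, and leaving out each library in turn. Added after seeing the data were the block within genotype, only barcodes with at least 10000 UMIs, both together, and totals without cluster 1. The share of cluster 27 at like depth was compared, also added after seeing the data, within bins of UMIs of equal width on the log scale, by the Mantel-Haenszel ratio of each pair of same-numbered libraries. Figures were drawn with matplotlib 3.10.9. No trajectory or cell-to-cell test was run, and cells were not used as replicates.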

Results

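Root protoplasts of wild-type Col-0 and of the FERONIA mutant fer-4 were compared after mock treatment and after the peptide RALF1, with 3 libraries per group. After filtering, 44512 cells were kept in Col-0 mock, 38030 in Col-0 RALF1, 26255 in fer-4 mock and 27223 in fer-4 RALF1. All kept barcodes are called cells here and form the total of the shares. They include cluster 1, without markers of any class, which made up 16.8% to 34.4% of a library. Many barcodes were shallow: 56.7% to 82.7% of those deposited lay within 2-fold of the smallest UMI count of their library. Cells had a median of 3260 to 7103 UMIs and 1679 to 2783 detected genes, depending on the library. The libraries of Col-0 mock held 182.6, 180.5 and 106.7 M UMIs in replicates 1 to 3, those of Col-0 RALF1 147.7, 147.8 and 117.1 M, those of fer-4 mock 132.7, 92.3 and 90.098 M, and those of fer-4 RALF1 147.5, 65.3 and 92.9 M. The share of mitochondrial UMIs was 0.326% ± 0.0773 in Col-0 mock, 0.336% ± 0.0914 in Col-0 RALF1, 0.572% ± 0.172 in fer-4 mock and 0.878% ± 0.522 in fer-4 RALF1 (SD, n = 3). Between the mock groups, an exact permutation test (two-sided) of this share gave p = 0.1, the smallest that 3 against 3 libraries allow. In a principal component analysis of the summed counts, the first component held 69.4% of the variance and the second 9.18%.

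FER itself was nearly absent from fer-4. In CPM without TMM factors, FER (AT3G51550, chromosome 3) was at 100.3 ± 11.9 in Col-0 mock, 99.1 ± 8.71 in Col-0 RALF1, 0.234 ± 0.0523 in fer-4 mock and 0.228 ± 0.140 in fer-4 RALF1 (SD, n = 3). This corresponds to 48100, 41177, 72 and 57 UMIs summed over the libraries of each group. The neighbouring gene DGAT2, which encodes a diacylglycerol acyltransferase, was at 52.9 ± 8.93 CPM in Col-0 mock, and in fer-4 it held 4 UMIs in mock and 2 with RALF1. AT3G51530 stood at 5.90 CPM and AT3G51540 at 11.1 CPM in Col-0 mock. In fer-4 AT3G51530 was listed at 0 in all libraries, and AT3G51540 held 2 UMIs, both with RALF1. On the other side of FER, AT3G51560 was higher in fer-4 mock by 4.25 ± 0.56 on the log2 scale (edgeR, Benjamini-Hochberg adjusted p = 0.00275), and AT3G51570 by 5.55 ± 0.56 (adjusted p = 0.000716), from 0.0697 to 3.25 CPM. AT3G51510, next to DGAT2, was higher by 0.89 ± 0.17 (adjusted p = 0.00884). The next genes, AT3G51500 (adjusted p = 0.289) and AT3G51580 (adjusted p = 0.326), did not pass the test. Further out, AT3G51470 fell (-1.92, adjusted p = 0.0301), while TMT3 (2.82, adjusted p = 0.0244) and LTP12 (2.73, adjusted p = 0.0260) rose. Some of these rises were near the floor, with 5 and 27 UMIs for TMT3, 18 and 87 for LTP12 and 8 and 103 for AT3G51560 in Col-0 and fer-4 mock. Of 15974 genes expressed in Col-0 at 1 CPM or more, 5 were at 1% or less of the Col-0 level in every fer-4 library, and 4 of these were FER, DGAT2, AT3G51530 and AT3G51540. The fifth was AT2G01422.

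**Figure D1:**
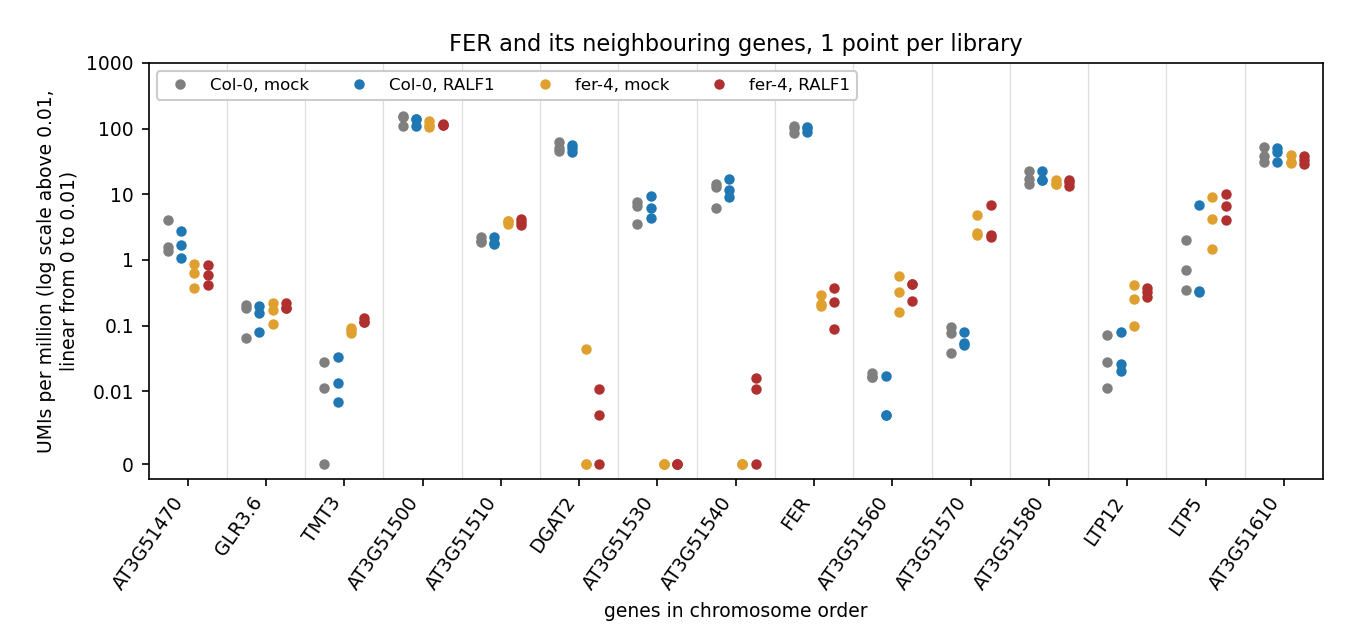
CPM without TMM factors (vertical axis, log scale above 0.01 and linear below) for FER and its neighbours in chromosome order (horizontal axis), with 1 point per library, coloured by group. FER, DGAT2, AT3G51530 and AT3G51540 are near 0 in every fer-4 library, and FER stays at 0.0882 to 0.368 CPM there against 87.2 to 110 CPM in Col-0.

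Across the whole root, fer-4 mock differed from Col-0 mock in 2829 of 21249 tested genes, of which 1238 rose and 1591 fell. QQS, a gene known to affect starch content, rose by 6.22 ± 0.29 on the log2 scale, from 0.890 ± 0.103 to 66.4 ± 17.4 CPM with TMM factors (SD, n = 3; adjusted p = 6.37e-07). PBL15, a receptor-like cytoplasmic kinase known from the Casparian strip barrier of the endodermis, rose by 2.87 ± 0.39 (adjusted p = 0.00282), and the trypsin inhibitor ATTI1 by 2.61 ± 0.51 (adjusted p = 0.0106). The transporter DTX14 rose by 2.59 ± 0.37 and LEA7, a late embryogenesis abundant protein, by 2.82 ± 0.54. The defensin PDF1.4 rose by 3.47 ± 0.80 (adjusted p = 0.0191), EARLI1 by 3.06 ± 0.88 (adjusted p = 0.0416) and GSTU12, a glutathione transferase, by 2.55 ± 0.61 (adjusted p = 0.0220). The arabinogalactan protein gene FLA6 fell by 3.59 ± 0.50 (adjusted p = 0.00330), the wall enzyme gene XTH12 fell by 3.45 ± 0.57, UCC3 fell by 3.43 ± 0.61 and AT1G67910 fell by 3.82 ± 0.70. AT4G12520 fell from 1133 to 101 CPM (-3.48 ± 0.61), and MRD1 to 0.657 CPM (-5.20 ± 1.07, adjusted p = 0.0124). These genes were taken from those without overlap between the 3 fer-4 mock and 3 Col-0 mock libraries, which made up 33.3% of all tested genes, where chance gives 10%. Some are leading genes of clusters whose mean share differed the same way: PBL15 of cluster 27 (0.183% of Col-0 mock and 1.38% of fer-4 mock), LEA7 of root cap cluster 6 (2.21% and 6.42%), PDF1.4 of cluster 16 (1.25% and 3.12%), and XTH12 and UCC3 of root hair cluster 15 (3.55% and 1.29%).

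PIF3, a light-signalling transcription factor, rose in fer-4 from 0.960 ± 0.254 to 1.88 ± 0.457 CPM (0.97 ± 0.28, edgeR adjusted p = 0.0405), higher in all 3 libraries. Its call was lost without Col-0 mock replicate 2 (adjusted p = 0.142) or 3 (0.0791), Col-0 RALF1 replicate 2 (0.0512), fer-4 mock replicate 1 (0.167) or 2 (0.0806), or fer-4 RALF1 replicate 2 (0.0502). It was also lost with only the groups compared (0.0737), with equal cell numbers per class (0.201) and with only barcodes of at least 10000 UMIs, called deep barcodes here (0.063). The mechanosensitive channel gene PIEZO (AT2G48060) was at 6.21 CPM in Col-0 and 5.63 CPM in fer-4 (-0.14 ± 0.22, adjusted p = 0.694). The RALF1 gene rose from 68.5 ± 4.22 to 139 ± 33.2 CPM (1.02 ± 0.23, adjusted p = 0.0179), a call lost without Col-0 mock replicate 2 (0.0681) or fer-4 mock replicate 1 (0.0796). In CPM without TMM factors it was at 616 and 1102 in the endodermis and 188 and 408 in non-hair epidermis of Col-0 and fer-4 mock. In pericycle it was at 88.6 and 61.1, in phloem and companion cells 31.7 and 29.4, and in root cap 24.2 and 24.2. In root hair cells it was at 27.05 and 32.0 and in xylem 41.0 and 44.5. Endodermal cells held 7326 and 26728 of its UMIs, so its whole-root level also depends on their share of UMIs. Without Col-0 mock replicate 2, fer-4 mock replicate 1 or fer-4 mock replicate 2, the number of called genes in the whole root dropped to 752, 736 and 854. Among 48 called genes named here or with the gene lists, 23 were called whichever library was left out, QQS, PBL15, FER, FLA6 and XTH12 among them. Calls were lost for PDF1.4 without fer-4 mock replicate 1 (0.0679) or 2 (0.0519), for GSTU12 without Col-0 mock replicate 2 (0.0958) or fer-4 mock replicate 1 (0.0949), and for MRD1 without fer-4 mock replicate 1 (0.0642) or 2 (0.0618). EARLI1 lost its call without Col-0 mock replicate 1 (0.0607), 2 (0.161) or 3 (0.0742), Col-0 RALF1 replicate 3 (0.0530), fer-4 mock replicate 1 (0.182) or 2 (0.0657), or fer-4 RALF1 replicate 3 (0.0513), and with equal cell numbers per class (0.0631) or deep barcodes alone (0.0988). EARLI1 and PDF1.4 lead cluster 30, which held 1.92% of fer-4 mock replicate 1, 3.80% of fer-4 RALF1 replicate 1 and at most 0.209% of any other library. Of the 48 genes, 24 were not called without fer-4 mock replicate 1, 21 without fer-4 mock replicate 2, 19 without Col-0 mock replicate 2 and 6 without Col-0 mock replicate 1, and at most 2 without any other library. With equal cell numbers per class and library, 1236 genes were called and the share that rose went from 43.76% to 51.86%. This setting held only the named classes, each cut to its smallest library, from 103 cells of non-hair epidermis to 599 of root cap per library. Calls lost under it can thus reflect fewer or other cells as well as the class mixture.

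**Figure D2:**
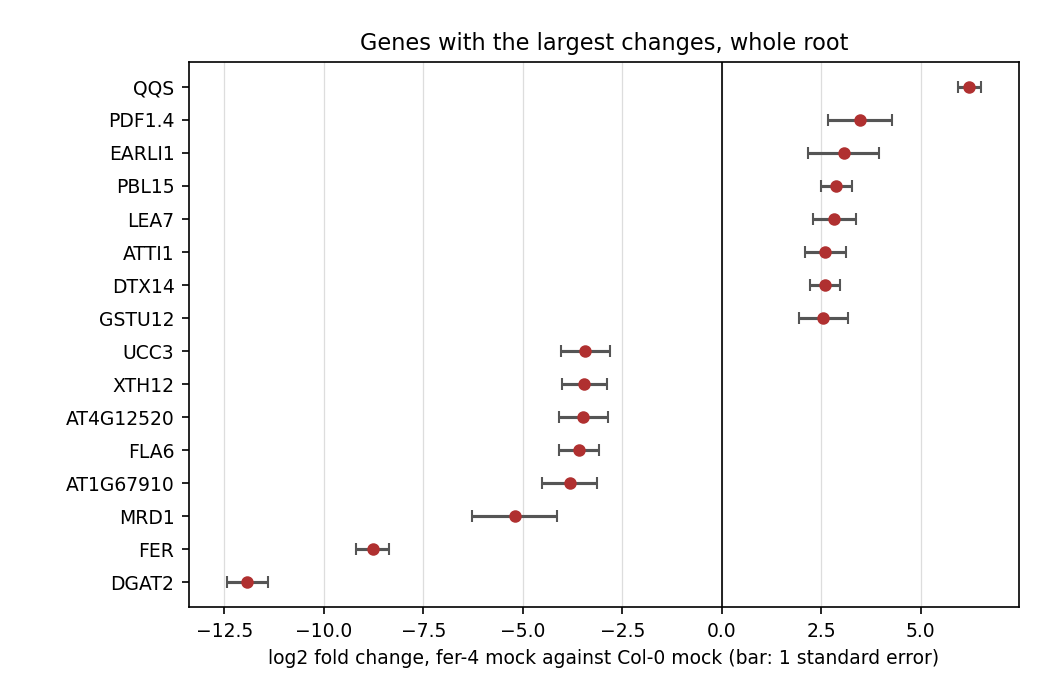
Log2 fold change of fer-4 mock against Col-0 mock (horizontal axis) for the 8 largest rises and the 8 largest falls under the rule for named genes (vertical axis), with points for edgeR estimates and bars for 1 SE. QQS stands at 6.22 ± 0.29 and FER at -8.78 ± 0.40, while the estimate for DGAT2, with 4 UMIs in fer-4 mock, depends on the prior count.

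Of 20 jasmonate genes, 9 rose and 0 fell in fer-4 mock against Col-0 mock (adjusted over the list alone, 15 rose), among them the synthesis genes LOX4 (1.81 ± 0.28, adjusted p = 0.00461), LOX3 (1.86), OPR3 (1.12 ± 0.18) and CYP74A (1.35). Of 15 early wound and stress transcription factors, 4 rose and 0 fell (4 over the list alone), including ERF2 (1.18 ± 0.22, adjusted p = 0.00800) and ERF6 (1.63). Of 15 ethylene genes, 6 rose and 0 fell (7 over the list alone), including the synthesis gene ACS8 (1.48) and EBF2 (0.74). Of 19 immunity genes, 3 rose and 0 fell (7 over the list alone). These were EXL1 (2.48 ± 0.41), CYP71A12, an enzyme of indolic defence compounds (4.31 ± 0.79), and the kinase MPK3 (1.10). Of 10 phosphate starvation genes, 2 rose (3 over the list alone): the galactolipid synthase MGD3 (1.49) and the ribonuclease RNS1 (1.63, from 200 to 620 CPM). RNS1 is a leading gene of cluster 16, whose mean share, given above, was higher in fer-4 mock. Of 17 abscisic acid genes, KIN2 alone rose (1.29, adjusted p = 0.0277; 1 over the list alone). The camera test with a preset correlation gave adjusted p = 6.15e-08 for jasmonate, 8.10e-05 for the wound factors, 0.00151 for ethylene, 6.05e-05 for immunity, and 0.00715 for both phosphate starvation and abscisic acid. With an estimated correlation none of these held: adjusted p = 0.202 for the first 4 lists, 0.292 for phosphate starvation and 0.448 for abscisic acid. The fry test, which asks whether a list's genes move one way and compares them with no other genes, gave adjusted p = 0.00864 for jasmonate, 0.0112 for wound factors, 0.00831 for ethylene, 0.0157 for immunity, 0.0374 for phosphate starvation and 0.0645 for abscisic acid.

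Of 24 root hair genes, 13 fell and 0 rose in fer-4 mock (19 fell, adjusted over the list alone), such as XTH26 (-2.58 ± 0.41, edgeR adjusted p = 0.00526) and XTH12. Root hair cells made up 6.42% of cells in Col-0 mock and 3.18% in fer-4 mock (adjusted p = 0.243). Of 22 genes of the FER receptor complex and its partners, 9 fell and 1 rose (11 and 3 over the list alone). Those that fell included the FER relatives THE1 (-1.63 ± 0.31, adjusted p = 0.00921) and HERK1 (-1.23), the co-receptor LLG1 (-0.99) and the proton pump HA2 (-0.98), while the kinase AT2G39360 rose (0.57). Of 6 heat shock genes, HSP17.6 (-0.58, adjusted p = 0.0107) and the factor HSFA2 (-1.10) fell, and the same 2 genes over the list alone. The camera test gave adjusted p = 4.86e-12 for root hair, 6.05e-05 for the FER complex and 0.0175 for heat shock. With an estimated correlation these were adjusted p = 0.202, 0.202 and 0.292. The fry test gave adjusted p = 0.0150, 0.00864 and 0.00864. The heat shock call was lost without Col-0 mock replicate 1 (0.0649) and with deep barcodes alone (0.181).

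The other lists were not called as sets in fer-4 against Col-0 by camera. In the mechanosensing list, the touch genes CML12 (1.24 ± 0.23) and XTH22 (1.40) rose and the channel gene MCA1 fell (-0.97 ± 0.17), with 3 up and 1 down of 8 over the list alone (adjusted p = 0.291; 0.454 with an estimated correlation). In the cell wall list, 3 of 21 genes rose, such as ATEXPA1 (0.83) and XTH23 (1.02), and 5 fell, such as ATXTH17 (-3.20 ± 0.46) and the cellulose synthase CESA3 (-0.67), with 6 up and 8 down over the list alone (adjusted p = 0.851; 0.842 with an estimated correlation). Of 8 RALF peptides, RALF1 and RALFL34 (0.70) rose and RALFL24 (-1.54) fell, with 2 up and 2 down over the list alone (adjusted p = 0.776). PIF3 was the sole call among 9 genes of PIF and light signalling, also over the list alone (adjusted p = 0.658). In the auxin list the synthesis gene YUC8 (0.97 ± 0.19) and LBD16 (0.78) rose, of 23, and 4 rose over the list alone (adjusted p = 0.291). In the iron list 3 of 14 fell, ORG3 (-2.27) and the regulator FIT (adjusted p = 0.0205) among them, with 1 up and 3 down over the list alone (adjusted p = 0.291; 0.0123 with equal cell numbers per class). Of 11 cell division genes CDKB2-2 alone rose (1.00), also over the list alone (adjusted p = 0.0762). Of 4 tested photosynthesis genes 0 were called (edgeR), PSAF with 1.78 and adjusted p = 0.134, or 3.14 and 0.0251 without Col-0 mock replicate 1, and no set test was made.

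Between fer-4 mock and Col-0 mock, 5146 of 14888 tested genes were called in the endodermis as a whole (2364 up, 2782 down), but within its single clusters 759 in cluster 18, 91 in cluster 27 and 531 in cluster 28. The other named classes had 1046 in phloem and companion cells, 963 in root hair cells, 848 in non-hair epidermis, 738 in root cap, 458 in pericycle and 148 in xylem. The classes differ in cell number, depth and mixture of clusters, so these counts do not rank the size of the effect. In the endodermis QQS rose by 7.25 ± 0.35 (edgeR adjusted p = 3.75e-07), the sulfate transporter family gene SULTR3;3 by 3.75 ± 0.40 and PDF1.4 by 3.56 ± 0.54, while AT2G45180 fell by 4.89 ± 0.53 (adjusted p = 0.000295). AT2G45180 also fell in phloem and companion cells (-3.62) and is a leading gene of cluster 7, whose share was lower in fer-4 mock, and whether RNA of those cells lies behind its fall was not tested. In phloem and companion cells GRXS5, a glutaredoxin, rose by 5.18 ± 0.83 (adjusted p = 0.00462). In non-hair epidermis AT5G52670 rose by 7.45 ± 0.66 (adjusted p = 0.000104) and the immunity gene FMO1 by 4.54 ± 0.67. In root hair cells the potassium transporter gene POT5 rose by 5.21 ± 0.62 (adjusted p = 0.00234). Of the root hair genes tested in each class, 18 of 21 fell in the endodermis, 11 of 24 in root cap, 10 of 22 in phloem and companion cells, 6 of 21 in non-hair epidermis, 4 of 24 in root hair cells, 4 of 19 in xylem and 3 of 22 in pericycle. Of the jasmonate genes, 9 of 18 rose and 1 fell in the endodermis, while 9 of 18 rose in phloem and companion cells, 7 of 18 in pericycle, 5 of 18 in root cap, 5 of 18 in non-hair epidermis, 4 of 18 in root hair cells and 4 of 19 in xylem. Cluster 27, a group of endodermal cells with a median of 37908.5 UMIs, made up 6.07% of endodermal cells in Col-0 mock and 33.2% in fer-4 mock, and 19.9% and 72.5% of endodermal UMIs. Cluster 22 made up 33.5% and 47.4% of the non-hair epidermis, cluster 13 44.7% and 59.2% of the root hair cells, and cluster 23 50.9% and 60.5% of the xylem, in Col-0 and fer-4 mock. The calls summed over classes numbered 9347, or 3999 without Col-0 mock replicate 2, 3950 without fer-4 mock replicate 1 and 5526 without fer-4 mock replicate 2.

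The level of FER in the cell classes of Col-0 mock was not tested between classes. In CPM without TMM factors its mean was highest in root hair cells (178 ± 25.1) and non-hair epidermis (155 ± 14.7), followed by endodermis (119 ± 14.6), pericycle (85.4 ± 6.44), xylem (75.8 ± 5.62), phloem and companion cells (70.6 ± 4.45) and root cap (48.3 ± 1.3004; SD, n = 3). In fer-4 mock its mean was at most 0.758 CPM in any class. PIF3 rose in the endodermis of fer-4, from 1.47 ± 0.790 to 4.41 ± 0.794 CPM, or 18 to 106 UMIs over 3 libraries (1.44 ± 0.45, edgeR, p adjusted over classes = 0.0296). This call was lost without Col-0 mock replicate 3 (0.131), fer-4 mock replicate 1 (0.0543) or fer-4 mock replicate 3 (0.0955), with deep barcodes alone (0.0921) and with 1 replicate block over all libraries (0.0512). The RALF1 gene rose in the endodermis from 616 to 1102 CPM (0.73 ± 0.24, adjusted p = 0.0331) and in non-hair epidermis from 188 to 408 CPM (1.18 ± 0.35, adjusted p = 0.0331). Cluster 27 held 19.9% of endodermal UMIs in Col-0 mock and 72.5% in fer-4 mock. In Col-0 RALF1 its UMI share and the endodermal means of PIF3 and the RALF1 gene all lay between those of these groups. A changed mixture of clusters thus cannot be told from a rise within endodermal cells. The mixture within non-hair epidermis differed as well. PIEZO was called in no class between fer-4 mock and Col-0 mock, except with deep barcodes alone in non-hair epidermis (-1.07, adjusted p = 0.0279).

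The share of root cap cells was higher in fer-4 mock than in Col-0 mock, and that of non-hair epidermis was lower. Root cap cells made up 21.7% ± 7.65 of fer-4 mock and 7.95% ± 3.31 of Col-0 mock (SD, n = 3; 1.45 ± 0.44, edgeR adjusted p = 0.0427). Non-hair epidermis made up 2.15% ± 1.03 and 6.65% ± 1.01 (-1.63 ± 0.39, adjusted p = 0.0190). Phloem and companion cells made up 5.51% ± 0.472 and 3.66% ± 0.227 (0.59 ± 0.20, adjusted p = 0.0495). In each of these classes all 3 fer-4 mock libraries lay on one side of all 3 Col-0 mock libraries, and an exact permutation test (two-sided) gave p = 0.1, the smallest possible. The root cap call was lost without Col-0 mock replicate 2 (0.159) or 3 (0.100), Col-0 RALF1 replicate 2 (0.0659), fer-4 mock replicate 1 (0.120) or 2 (0.107), or fer-4 RALF1 replicate 2 (0.0521) or 3 (0.0518). The phloem call was lost in 11 of the fits without 1 library, all but that without fer-4 RALF1 replicate 1, at 0.0518 to 0.159, and among deep barcodes (0.0945). The non-hair call was lost without Col-0 mock replicate 2 (0.0638), fer-4 mock replicate 1 (0.0598) or fer-4 mock replicate 2 (0.0770). The number of called shares was 0 without any 1 of these 3 libraries, and 1 without Col-0 mock replicate 3, Col-0 RALF1 replicate 2, fer-4 RALF1 replicate 2 or fer-4 RALF1 replicate 3. The endodermis held 3.00% of Col-0 mock and 4.11% of fer-4 mock (0.45, adjusted p = 0.0933). Among barcodes with at least 10000 UMIs, endodermis was higher in fer-4 mock (1.41, adjusted p = 0.00858) and root hair cells lower (-1.51, adjusted p = 0.0255). With RALF1, the root cap share was 8.96% in Col-0 and 20.0% in fer-4.

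**Figure D3:**
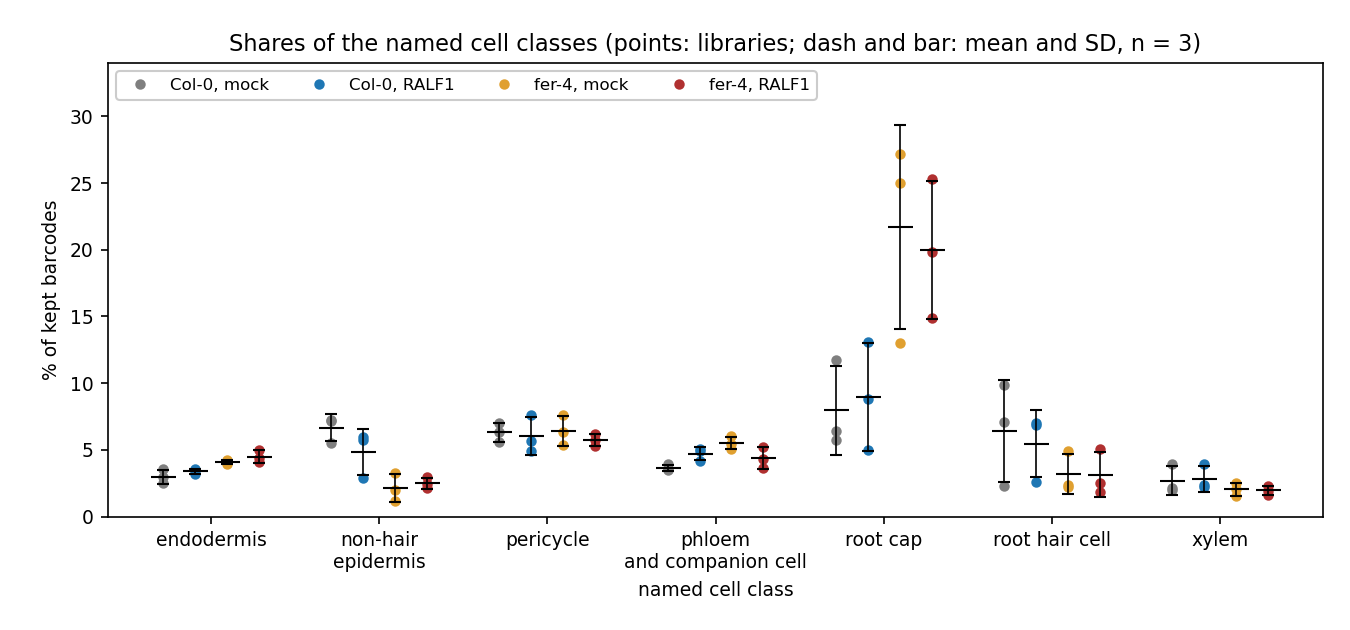
Share of kept barcodes in % (vertical axis) for the 7 named cell classes (horizontal axis), with 1 point per library coloured by group, and a dash and bar for mean and SD (n = 3). Root cap cells reach 21.7% in fer-4 mock against 7.95% in Col-0 mock, and non-hair epidermis 2.15% against 6.65%.

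RALF1 treatment of Col-0 for 2 h left the summed expression of the whole root with 0 genes called by edgeR of 21249 tested, with 317 at an unadjusted p under 0.05. This is a smaller share than the 0.05 that chance alone gives. Genes without overlap between the groups made up 3.19% of those tested, where chance gives 10%. Same-numbered libraries resembled each other, which the test without the block ignores, so it was conservative here. The 0 calls thus do not show that RALF1 had no effect. DESeq2 called 5, which are named here after their values were seen: IRT1 (3.02, adjusted p = 0.000174), AtMYB74 (0.99, adjusted p = 0.0167) and CPRD49 (0.88, adjusted p = 0.0414) were higher with RALF1, and AT1G15625 (-1.51, adjusted p = 0.0147) and AT4G30450 (-1.10, adjusted p = 0.0269) were lower. The transcription factor gene AtMYB74 was at 5.72 CPM in mock and 11.4 CPM with RALF1 (1.00 ± 0.20, edgeR adjusted p = 1.00; 1.33 and adjusted p = 0.0350 with equal cell numbers per class). PBL15, TIP2-2 and TAT3 were also chosen after their values were seen, and none was called (edgeR adjusted p = 1.00 for each). PBL15 was at 13.2 and 33.1 CPM (1.33 ± 0.37; 1.34 ± 0.13 and adjusted p = 0.0601 with the replicate block), where cluster 27, of which PBL15 is the leading gene, held 6.07% and 21.8% of endodermal cells. The water channel gene TIP2-2 was at 387 and 145 CPM (-1.41) and TAT3, an aminotransferase gene, at 492 and 969 CPM (0.98). AT1G15625 was the single gene called with the replicate block, falling from 8.49 to 3.01 CPM (-1.45 ± 0.11, adjusted p = 0.0245). It is a leading gene of cluster 22, which held 2.18% of cells in mock and 1.29% with RALF1. With the block and only deep barcodes, 4 genes were called: AT1G15625 (-1.56), AT2G01900 (-1.42), TIP2-2 (-1.36) and AtMYB74 (1.10). FER (-0.03), PIF3 (0.28), PIEZO (0.08) and the RALF1 gene (0.26) were not called.

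The iron transporter gene IRT1, chosen after its values were seen, passed the test adjusted over the list alone (edgeR, adjusted p = 0.000900) and not over all genes (adjusted p = 1.00). It was at 0.186 ± 0.0407 CPM in Col-0 mock and 1.51 ± 0.907 CPM in Col-0 RALF1 (3.02 ± 0.50), higher in all 3 RALF1 libraries, and at 0.229 ± 0.133 and 0.0800 ± 0.0302 CPM in fer-4 mock and RALF1. MSL9, a mechanosensitive channel gene, passed over its list alone (0.84 ± 0.23, adjusted p = 0.0257), and no member of the other lists did. It is a leading gene of cluster 16, which held 1.25% of cells in mock and 2.49% with RALF1. The 20 jasmonate genes rose as a set in Col-0 (camera adjusted p = 5.01e-08, median 0.38; adjusted p = 0.627 with an estimated correlation), with LOX3 at 0.63, TIFY10B at 0.63, CYP74A at 0.46 and VSP1 at -0.81. The 17 abscisic acid genes rose as a set (camera adjusted p = 0.0201, median 0.17; adjusted p = 0.627 with an estimated correlation), with RAB18 at 1.27. This second call was lost without Col-0 RALF1 replicate 1 (0.815) and with equal cell numbers per class (0.128), and without Col-0 mock replicate 2 the direction turned (0.796). The other 14 tested lists had camera adjusted p from 0.137 to 0.964, and the smallest fry adjusted p of any list was 0.924. In the phosphate starvation list the median was 0.07 and the mean -0.02, with the test pointing up. In the cell wall list they were 0.01 and -0.04, with the test pointing down. The number of called lists was 5 without Col-0 mock replicate 3, 1 without Col-0 RALF1 replicate 1, 6 without Col-0 RALF1 replicate 2 and 5 without Col-0 RALF1 replicate 3.

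In the cell classes of Col-0, edgeR called 0 genes for RALF1, with 4622 at an unadjusted p under 0.05 summed over classes, 2350 of them in the endodermis. Of the 14888 genes tested in the endodermis this is more than the 0.05 that chance gives, while each other class lay below that share. With the replicate number as a block within genotype, chosen after the data were seen, 1219 genes were called, of which 1194 lay in the endodermis (455 up, 739 down), 15 in root hair cells, 5 in pericycle, 3 in non-hair epidermis and 2 in phloem and companion cells. The water channel genes TIP2-2 and TIP2-3 fell both in pericycle (-1.36 and -1.06), with AT1G48750, AAP2 and AT4G33550, and in non-hair epidermis (-1.27 and -1.12), with AT1G15625, where cluster 22 held 33.5% of cells in mock and 26.9% with RALF1. AAP2 is a leading gene of cluster 20 of the phloem and companion cells. The genes called in phloem and companion cells were AT1G11450 (-1.76) and AT3G06962 (1.61). In the endodermis, cluster 27 held 6.07% of cells in mock and 21.8% with RALF1. The endodermal genes that follow were also chosen after their values were seen. With the block, LIP2 rose from 13.1 to 43.8 CPM (1.75 ± 0.14, edgeR adjusted p = 0.00209), CYP94B1, an enzyme of jasmonate breakdown, from 11.3 to 35.8 CPM (1.60 ± 0.28, adjusted p = 0.0141), and ATL45 from 83.3 to 234 CPM (1.59 ± 0.18, adjusted p = 0.00612). The signalling peptide gene CLE5 fell from 60.7 to 6.18 CPM (-3.06 ± 0.50, adjusted p = 0.0123) and AT1G62510 from 79.9 to 14.1 CPM (-2.47 ± 0.20, adjusted p = 0.00209). The arabinogalactan protein gene FLA8 (-1.87 ± 0.27) and the invertase inhibitor gene C/VIF2 (-1.77 ± 0.27) fell as well. Within cluster 18 alone, AT1G62510 (-2.22, adjusted p = 0.00375) and C/VIF2 (-1.47, adjusted p = 0.0298) were still called. CYP94B1 (1.26, adjusted p = 0.358), ATL45 (0.76, adjusted p = 0.150), CLE5 (-2.32, adjusted p = 0.109) and FLA8 (-1.30, adjusted p = 0.168) were not, and LIP2 had the opposite sign there (-0.41, adjusted p = 0.843). AT1G62510 and C/VIF2 are leading genes of cluster 7, where cortex markers were enriched, and CLE5, with an SD of 47.4 CPM in mock, leads cluster 24, neither of them endodermal by name. Whether free RNA or mixed-in cells of these clusters lie behind the falls was not tested. Of the cell wall list 8 fell and 1 rose (camera adjusted p = 7.00e-05; adjusted p = 0.112 with an estimated correlation), and of the FER complex list 7 fell and 3 rose (camera adjusted p = 0.00404; adjusted p = 0.112 with an estimated correlation). The abscisic acid list was called upward, with 3 up and 0 down (7.00e-05; 0.112 with an estimated correlation), and the root hair list downward, with 0 up and 1 down (0.0146; 0.657). The barrier receptor SGN3 fell by 0.49 ± 0.12 (adjusted p = 0.0428), while the Casparian strip genes CASP1 (0.03), MYB36 (0.12) and ESB1 (0.22) were not called. Within single endodermal clusters the block gave 37 calls in cluster 18 (29 up, 8 down), 0 in cluster 27 (710 at an unadjusted p under 0.05) and 28 in cluster 28 (6 up, 22 down).

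With the replicate block within genotype, cluster 27 of the endodermis rose in share after RALF1 in Col-0. It made up 0.183% ± 0.0545 of cells in Col-0 mock and 0.740% ± 0.171 with RALF1 (SD, n = 3), with 0.225% and 0.898%, 0.121% and 0.559%, and 0.202% and 0.764% in replicates 1 to 3. Without the replicate block the difference was 2.02 ± 0.54 on the log2 scale (edgeR adjusted p = 0.0871), and with it 2.03 (adjusted p = 7.05e-09). In fer-4 it made up 1.38% ± 0.730 in mock and 1.62% ± 1.10 with RALF1 (0.17, adjusted p = 0.867 with the block). Between the mock groups cluster 27 was higher in fer-4 by 2.91 ± 0.55 (adjusted p = 0.00318). Cluster 16, led by the stem cell niche gene WOX5 together with RNS1 and NIT1, made up 1.25% ± 0.618 of cells in Col-0 mock and 2.49% ± 1.05 with RALF1 (1.03, adjusted p = 0.000767 with the block), and 3.12% and 2.77% in fer-4 mock and RALF1. This call was absent without the block (1.00 ± 0.51, adjusted p = 0.998) and among deep barcodes with it (0.83, adjusted p = 0.238). Cluster 22 of the non-hair epidermis made up 2.18% of Col-0 mock and 1.29% of Col-0 RALF1 (-0.81, adjusted p = 0.0154 with the block; 0.998 without it). Without the block edgeR called the share of 0 of the 7 classes for RALF1 in Col-0, with 0 at an unadjusted p under 0.05. Among deep barcodes the difference in endodermis share was 0.90 ± 0.33 (edgeR unadjusted p = 0.0195, adjusted p = 0.371), and with the block the share was higher by 0.91 (edgeR adjusted p = 0.0374).

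**Figure D4:**
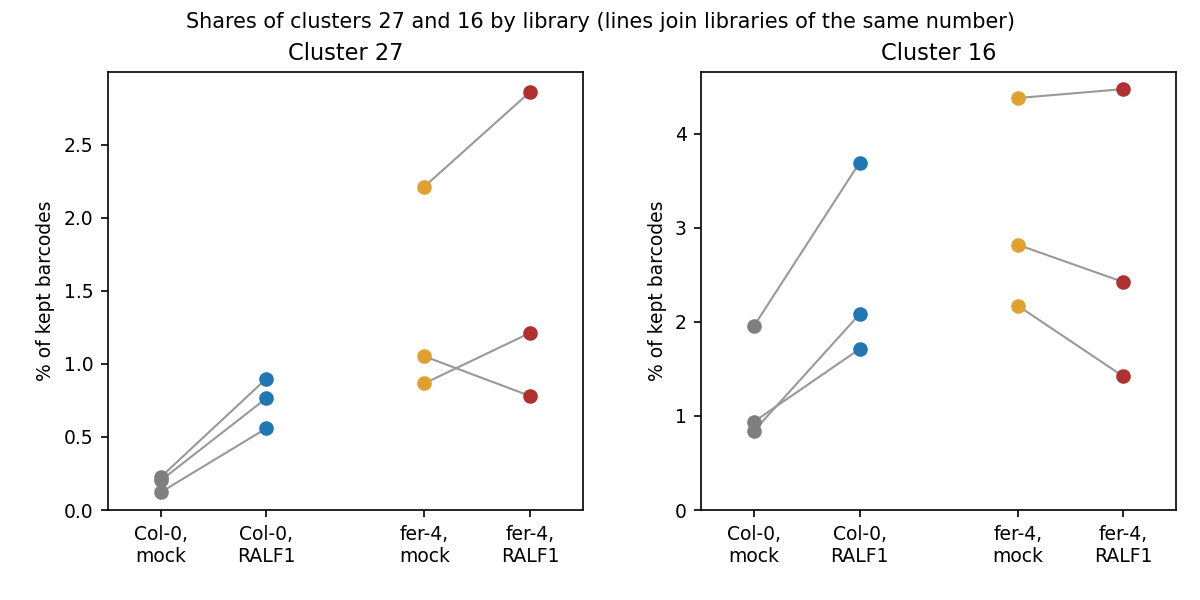
Shares of cluster 27 (left) and cluster 16 (right) in % of kept barcodes (vertical axes) by group (horizontal axes), with 1 point per library and lines joining mock and RALF1 libraries of the same number. In Col-0 cluster 27 went from 0.225% to 0.898%, 0.121% to 0.559% and 0.202% to 0.764%.

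In fer-4, RALF1 left 0 of 21249 genes called by edgeR in the whole root, with 176 at an unadjusted p under 0.05, and DESeq2 also called 0. The 176 are again a smaller share than the 0.05 that chance alone gives. Genes without overlap between the groups made up 4.85%, where chance gives 10%. FER (-0.24), PIF3 (0.03), PIEZO (0.27) and the RALF1 gene (0.13) were among those not called. The 24 root hair genes fell as a set (camera adjusted p = 4.67e-05, median -0.21; adjusted p = 0.723 with an estimated correlation), and so did the 10 phosphate starvation genes (camera adjusted p = 1.39e-05, median -0.35; adjusted p = 0.401 with an estimated correlation), with IPS1 at -0.85 and MGD3 at -0.76. The 17 abscisic acid genes also fell as a set (camera adjusted p = 0.0244, median -0.12; adjusted p = 0.723 with an estimated correlation). The root hair call was lost without fer-4 mock replicate 3 (0.0959) or fer-4 RALF1 replicate 2 (0.0842), and the abscisic acid call without fer-4 mock replicate 2 (0.377) or fer-4 RALF1 replicate 3 (0.497). The smallest fry adjusted p was 0.907. The 3 called lists became 6 without Col-0 RALF1 replicate 1, 7 without fer-4 mock replicate 1 and 8 without fer-4 RALF1 replicate 1. Among the classes, AT2G37750 in xylem was the single call without the replicate block, falling from 1608 ± 81.4 to 653 ± 63.9 CPM (-1.30 ± 0.16, edgeR adjusted p = 0.0144), against 1380 and 1622 CPM in Col-0 mock and RALF1. The mixture within xylem differed as well, with cluster 25 at 47.8% of xylem UMIs in fer-4 mock and 37.9% with RALF1, against 59.2% and 69.1% in Col-0. The call of AT2G37750 was lost without Col-0 mock replicate 3 (0.0533), fer-4 mock replicate 1 (0.0925), or fer-4 RALF1 replicate 1 (0.158), 2 (0.168) or 3 (0.0829), and the gene was chosen after its values were seen. The count of class calls was 2 without fer-4 mock replicate 2 and 4 without fer-4 mock replicate 3. With the replicate block within genotype, AT1G16022 (-1.91), PER52 (2.42), AT3G03440 (-1.02), AT3G48450 (1.15) and CEN (-1.70) were called in pericycle. In xylem the block called ATL72 (-3.43), EXLA1 (-1.33), AT2G34355 (-1.33) and AT2G37750 (-1.30). All were chosen after their values were seen, and CEN is a leading gene of cluster 19 of the phloem and companion cells.

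The responses of the genotypes to RALF1 were compared directly by the interaction. edgeR called 0 of 21249 genes, with 163 at an unadjusted p under 0.05, and DESeq2 called 1, IRT1 (-4.52, adjusted p = 0.000309). The 163 are also a smaller share than the 0.05 that chance alone gives. In the classes edgeR called 0, with 3090 at an unadjusted p under 0.05. IRT1 had an edgeR interaction of -4.50 ± 0.75, with adjusted p = 0.000972 over the list alone. AT2G37750 in xylem, where the UMI share of cluster 25 was lower with RALF1 in fer-4 and higher in Col-0 (not tested), was called with 1 replicate block over all libraries (-1.53, adjusted p = 0.0348). PIEZO in the endodermis was called only with the block within genotype. In CPM without TMM factors it was at 6.57 and 4.34 in Col-0 mock and RALF1, and at 4.18 and 6.43 in fer-4 mock and RALF1. As sets, the abscisic acid genes (camera adjusted p = 0.000119, median -0.28; 3.34e-06 with the block), the phosphate starvation genes (0.00242, median -0.40; 0.000396 with the block) and the jasmonate genes (0.0174, median -0.22; 0.0574 with the block) were lower in the response of fer-4 than in that of Col-0. With an estimated correlation each had adjusted p = 0.699, and the smallest fry adjusted p was 0.841. RAB18 (-1.36) and RNS1 (-0.86) had interactions in this direction without being called. RNS1 is a leading gene of cluster 16, whose share, given below, had an interaction of the same sign. The abscisic acid and the phosphate calls were lost without Col-0 mock replicate 2 (0.283 for both) or Col-0 RALF1 replicate 1 (0.0571 for both). The phosphate call was also lost without fer-4 mock replicate 1 (0.105) or fer-4 RALF1 replicate 2 (0.113). The jasmonate call was lost without Col-0 mock replicate 1 (0.0788) or 2 (0.782), Col-0 RALF1 replicate 1 (0.473), fer-4 mock replicate 1 (0.220), or fer-4 RALF1 replicate 1 (0.567) or 3 (0.275), and with equal cell numbers per class (0.742). The number of called lists was 5 without Col-0 mock replicate 3, 0 without Col-0 RALF1 replicate 1 and 6 without Col-0 RALF1 replicate 3. In the iron list the median was 0.04 and the mean -0.12, with the test pointing down. For cluster 27 the interaction of its share with the block was -1.86 (adjusted p = 0.000156), and for cluster 16 it was -1.28 (adjusted p = 0.00439). Neither was called without the block (-1.78 and -1.17, adjusted p = 0.785 for both), nor was cluster 16 among deep barcodes with it (adjusted p = 0.453).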

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

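The tests of cluster shares with the replicate block within genotype, and the test of RNA-rich barcodes, were chosen only after the result was seen. By the interaction test, the RALF1 responses of fer-4 and Col-0 differed in 3 gene lists and, only with that block, in the shares of 2 clusters. For the jasmonate list camera gave adjusted p = 0.0174, for the abscisic acid list 0.000119 and for the phosphate starvation list 0.00242, each with adjusted p = 0.699 with an estimated correlation. With the replicate block the jasmonate list was no longer called (camera adjusted p = 0.0574). For the share of cluster 16 edgeR with the replicate block gave -1.28 (adjusted p = 0.00439), and for cluster 27 -1.86 (adjusted p = 0.000156). Without the block adjusted p was 0.785 for both, and among deep barcodes with it 0.453 for cluster 16. In Col-0 both clusters had a higher share in all 3 RALF1 libraries than in the mock library of the same number.

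After RALF1, the endodermis of Col-0 held more cells of cluster 27, and 1194 of its genes were called with the replicate block. More RNA-rich barcodes of every class would leave the share unchanged at like depth, but within bins of UMIs per barcode the log2 ratio was 1.76 (SE 0.190 over 3 pairs of libraries; 1.82, 2.05 and 1.40), against 2.00, 2.20 and 1.92 over all barcodes. Leading genes alone do not set the cluster apart, since 94.6% of its cells fell in 1 cluster when clustered without its 300 leading genes. A changed mixture of endodermal clusters and a change within them cannot be told apart: the called genes had in cluster 18 a median of 0.522 of their change in the class (quartiles 0.348 and 0.693), between none and all of it. An effect of RALF1 on these cells, or on how readily they leave the tissue as protoplasts, may lie behind either, and neither was tested.

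For RALF1 in Col-0 and in fer-4 the 10 splits of 6 libraries are too few for a share under 0.05. In Col-0 the real split called 0 genes in the whole root (highest other 0, 10 splits with as many), 0 over classes (highest other 311, 10 splits), 2 lists (highest other 7, 6 splits) and 0 shares (highest other 0, 10 splits). The 311 calls may point to a structure of the samples: they came from a split that keeps pairs of mock and RALF1 libraries together, while those that part all 3 pairs, as the real one does, called at most 0. With the block, the real split called 1219 over classes and the other splits that part all pairs 0 (1 of 4 splits), again too few. In fer-4 the real split called 0 genes (highest other 0, 10 splits), 1 over classes (highest other 4, 5 splits), 3 lists (highest other 6, 8 splits) and 0 shares (highest other 0, 10 splits). For the lists of the interaction chance cannot be excluded, as 69 of 100 drawn splits called as many as the real 3 (highest other 8). Its other counts say nothing on chance, since any split reaches a real count of 0: 100 of 100 for genes (highest other 1) and for shares (highest other 1), and 24 of 24 over classes. There the highest other, 209, came from 1 split that parts 4 of the 6 pairs, and most such splits called 0, so whether a structure of the samples lies behind it is open.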

How the results depend on the processing

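The replicate block within genotype and the fits on deep barcodes (at least 10000 UMIs), alone or with that block, were chosen after seeing the data. Of the counts that answer a comparison, 97 stayed within 1.5 times their value under another setting and 24 did not, and with 1 library left out 160 did and 32 did not. Among single genes, lists, levels and shares, 2113 kept their direction and side of the threshold, 68 fell below it and 16 passed it, while with 1 library left out 3634 kept both, 155 fell below, 50 passed and 1 reversed. The reversed one was the abscisic acid list for RALF1 in Col-0, at adjusted p = 0.796 without Col-0 mock replicate 2, within a range from 0.000240 to 0.815 over the fits without 1 library. The cause was not tested for any change of a result given here.

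With DESeq2 the whole-root counts were 5 for RALF1 in Col-0, 1 for the interaction and 4561 for fer-4 against Col-0, in place of 0, 0 and 2829. With equal cells per class they were 1 for RALF1 in Col-0 and 1236 for fer-4 against Col-0, and 1 list was called for RALF1 in Col-0 in place of 2. That setting also left out the unnamed clusters and many cells of the named classes. With only the groups compared, fer-4 against Col-0 gave 1343. With 1 replicate block over all libraries it gave 5815, and over classes 18970 in place of 9347, 359 in place of 0 for RALF1 in Col-0 and 1 in place of 0 for the interaction. The replicate block within genotype gave 1 in the whole root for RALF1 in Col-0 (4 with deep barcodes), and over classes 1219 for RALF1 in Col-0 and 9 in place of 1 for RALF1 in fer-4. It also ended the call of the jasmonate list for the interaction (0.0574) and made one for PIEZO in the endodermis for the interaction (1.18, adjusted p = 0.0452), and changed no other call among the named genes, lists, levels and class shares. With deep barcodes as well, it called the endodermis share for RALF1 in Col-0 (0.91, adjusted p = 0.0374). With no filter on low counts, 26 were called over classes for RALF1 in Col-0, 14 for RALF1 in fer-4 and 2 for the interaction (IRT1 in root hair cells and SARD4 in xylem, chosen after their values were seen). For RALF1 in fer-4, 15 were called over classes with equal cell numbers and 3 with deep barcodes (PDX13, AT2G37750 and AT4G22530 in xylem). With an estimated correlation 0 lists were called, in place of 2, 3, 3 and 9.

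Leaving out 1 library at a time, the whole-root counts ran from 0 to 0 for RALF1 in Col-0, for RALF1 in fer-4 and for the interaction, and from 736 to 3215 for fer-4 against Col-0. Over classes they ran from 0 to 2 for RALF1 in Col-0 (2 without Col-0 mock replicate 1 or 3), from 0 to 4 for RALF1 in fer-4, from 0 to 0 for the interaction and from 3950 to 10625 for fer-4 against Col-0. Called lists ran from 1 to 6, 2 to 8, 0 to 6 and 9 to 12, and called shares from 0 to 0 in the first 3 comparisons and from 0 to 3 in the last. No value exists for the interaction with only the groups compared, nor for non-hair epidermis at the lower clustering resolution, where no cluster took that name. In simulated data 54% of 2-fold changes were found for RALF1 in Col-0, 55% for RALF1 in fer-4 and 11% for the interaction, and 82%, 90% and 32% with the replicate block within genotype, so changes of this size or smaller can go uncalled. The changed genes had a mean of at least 10 CPM. They included 100 genes changed 4-fold beside the 100 changed 2-fold, so fewer 2-fold changes may be found in the real comparisons. For the block, the part of the spread that a pair shares was set in the simulation and not estimated from the data. How far depth limits this was not tested.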

Other observations

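The tests of the class mixture and of carried-over Col-0 RNA were chosen only after the result was seen. In all 7 named classes 10 genes rose and 14 fell in fer-4 mock against Col-0 mock. The jasmonate synthesis genes OPR3 and CYP74A, the defensin PDF1.4, the trypsin inhibitor ATTI1, the transporter DTX14 and QQS rose in each class. Besides FER, DGAT2 and AT3G51530, the genes that fell in each class included the wall enzyme genes ATXTH17 and XTH12, the methylesterase MES1, MRD1 and the mitochondrial chaperone HSP70-10. ATXTH17 leads cluster 9 of the non-hair epidermis, whose share was lower in fer-4 mock, and XTH12 is a leading gene of the root hair clusters 13 and 15. Less free RNA of those cells was not tested for either gene alone. In any class at all 3401 genes rose and 3362 fell.

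Some unnamed clusters also moved with genotype. Cluster 7, where the cortex markers AED3 and C/VIF2 were enriched, made up 5.17% ± 0.823 of cells in Col-0 mock and 1.21% ± 0.553 in fer-4 mock (SD, n = 3; -2.09 ± 0.36, edgeR adjusted p = 0.00293), with 5.43% and 1.41% after RALF1. Cluster 17, with 5 non-hair epidermis markers but also another class's marker, made up 2.86% and 1.16% in mock (-1.30, adjusted p = 0.0442), with 2.93% and 1.09% after RALF1. Clusters 2, 12 and 14, kept unnamed by the 25% limit, made up 7.39%, 2.39% and 2.68% of Col-0 mock, 8.46%, 3.21% and 2.78% of Col-0 RALF1, 7.89%, 2.52% and 1.69% of fer-4 mock and 7.11%, 1.92% and 2.33% of fer-4 RALF1. Cluster 30 had a higher share in fer-4 mock (adjusted p = 0.0442), with 1.92% of replicate 1 and 0.0597% and 0.0535% of replicates 2 and 3.

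Between fer-4 and Col-0 in mock, 2829 genes were called in the whole root, and root hair genes were lower also in classes other than root hair cells. Lower total depth of the fer-4 libraries is argued against, since 89.6% of the called genes were still called in the same direction with all libraries thinned to the shallowest, at 62.6 M UMIs. Thinning the sums does not address differences in UMIs per barcode. How much of the whole-root change came from a changed mixture of classes and how much from within classes cannot be told apart. With equal cells per class the called genes kept a median of 0.727 of their log2 change (quartiles 0.557 and 0.909, 99.4% of 2656 with the same sign), while 82300 cells had no named class. Within the named classes 148 (xylem) to 5146 (endodermis) genes were called. For those genes this argues against a changed mixture of classes as the sole source. A changed mixture of clusters within a class, or free RNA, may still add to these calls. Free RNA of root hair cells may account for part of the lower hair list in other classes, as its level in deep barcodes of these classes was 0.476 ± 0.0593 of that in shallower ones in Col-0 mock (SD, n = 3). An effect of genotype within the cells stays open.

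The 10 splits of the 6 mock libraries are too few for a share under 0.05. The real split called 2829 genes in the whole root (highest other 0), 9347 over classes (highest other 1), 9 lists (highest other 8) and 3 shares (highest other 0), and 1 split, the real one, reached each of these.

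FER and the 3 genes DGAT2, AT3G51530 and AT3G51540 beside it were at or near 0 in fer-4. Of 15974 genes expressed in Col-0, 5 were at 1% or less of the Col-0 level in every fer-4 library: these 4 and AT2G01422. A loss scattered over many expressed genes is thus argued against. Among runs of at least 3 neighbouring expressed genes, 1 was lost in every fer-4 library, that of these 4. A count of runs cannot register genes lost singly, such as AT2G01422. Carried-over RNA of Col-0 is argued against as the source of the 129 FER UMIs left in fer-4, since these held 6 DGAT2 UMIs where 67.0 would go with them, a ratio of 0.0895. A candidate explanation is a deletion or rearrangement next to the insertion in this stock, which the counts cannot decide without reads. Which of these 4 genes stands behind any other difference between the genotypes was not tested.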
